A study of Mus musculus with 5 samples.

How the data were processed

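Gene expression was measured on 5 arrays of mouse lung natural helper cells, innate lymphocytes that lack antigen receptors. Per the labels' protocols, 3 unstimulated samples were lysed straight after flow cytometric sorting, and 2 samples were kept for 3 days in 200 microlitres of medium with 60 ng/ml PMA and 500 ng/ml ionomycin before lysis. Total RNA was extracted with Trizol, and 6 micrograms were turned into biotin-labelled cRNA for a 1-colour Affymetrix array. Each sample's group and replicate number came from its title. The labels give the source as lung leukocytes, and the series' design text names the sorted population.

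The deposited values are log2 expression values from RMA (robust multi-array average), per the submitters' processing notes. The version of RMA, the software and the set of arrays normalized together were not given in the sources used here. The table held 35556 probe sets on each array, with minima of 0.80 to 0.91, medians of 5.63 to 5.66 and maxima of 12.9 to 13.0. There were no detection calls, so dim probe sets could not be set apart from background, and the number of arrays limits the precision. Of the 19938 genes tested, 12359 (62.0%) had a value shared by 2 or more arrays to 5 decimals, and 1304 had 1 value on all 5 arrays.

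Probe sets were named through the array platform's annotation. A single gene symbol was given for 21789 probe sets and several for 1621, and 12146 were not in the annotation table used here. Of the single-gene probe sets, 21698 matched the mouse gene table by Entrez number, 91 did not, and no symbol changed. Probe sets with several symbols named no gene, and those absent from the table are unnamed here. For the 999 genes with more than 1 probe set, the probe set with the highest mean over the 5 arrays was used. No coordinates are given, since no genome build is named in the sources used here.

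The stimulated and unstimulated samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no filter on dim probe sets). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and single genes are said to have risen or fallen only where called. The empirical Bayes prior had 0.649 degrees of freedom beside 3 residual ones. Differences are PMA and ionomycin minus unstimulated on the log2 scale, with the standard error (SE) of the fit, and n is 3 unstimulated and 2 stimulated arrays throughout. A permutation test of 3 against 2 arrays has 10 splits and a smallest exact p of 0.1, so none is reported.

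Before the data were examined, 36 gene lists were fixed. They covered products, receptors, transcription factors and sort markers of natural helper cells, activation, metabolism and growth, markers of 11 other cell types, and reference genes. Lists with 5 or more measured members, the reference genes apart, were tested with camera (preset correlation 0.01, Benjamini-Hochberg adjustment over 34 lists). Camera asks whether a list's genes moved further in 1 direction than the other genes. Each list was tested again with a correlation estimated from the data, and with fry, whose directional p asks whether a list's own genes move 1 way on balance. Beside each list, calls adjusted over the list alone are counted.

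The rule for naming genes was fixed at the same time. It took the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, without predicted genes, clones, small RNAs and antigen receptor segments. From each list it took up to 4 called members with the largest change. Members of the lists on secreted products, sort markers, receptors and lineage transcription factors could be named whatever their p. The genes Ifng, Il17a, Il17f, Gins1, Mki67, Ccl3, Ccl5, Ccl6, Cxcl10 and Xcl1 were named after their values were seen. So were other markers of lung cells, interferon and MHC class II genes, and Xist's sex-linked companions.

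Alternatives were an intensity trend or robust variances in eBayes, array weights, 2 filters on dim genes, other summaries of a gene's probe sets, 4 further normalizations, stricter thresholds, the replicate number as a block, and leaving out each array. Added after seeing the data were a fit with unstimulated array 3 as the lone unstimulated array, a fit without genes holding repeated values, and a fit without the lists of other cell types, the interferon list and sex-linked genes. Lists of FOXO1 targets, aminoacyl-tRNA synthetases, proteasome subunits, N-glycosylation genes and fatty acid synthesis genes were written after results had been seen, and were tested with heat shock factor targets in an adjustment of their own. Random lists matched on mean expression (10000 draws) gave the range for medians of lists on chosen arrays. Plots were made with matplotlib 3.10.9 in Python 3.11.15.

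The scripts were tested on simulated data drawn from the real genes' means and spreads, in 10 draws with 200 changed genes each among 19938. For this comparison, limma recovered 21.6% of genes changed by 0.58 log2, 43.8% at 1 log2, 70.0% at 2 log2 and 87.6% at 3 log2, and none with the wrong sign. Unchanged genes made up 6.54% of the calls. With the preset correlation, camera recovered 40 of 40 moved lists and called 0 of 300 unchanged ones. With an estimated correlation it recovered 21 of the 40. The simulated genes varied independently, and changed genes and moved lists were drawn from genes above the median expression. The simulation thus could not show false calls that come from members varying together. Estimated correlations in the real lists reached 0.887, for endothelial markers.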

Results

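Natural helper cells, also called group 2 innate lymphoid cells, are innate lymphocytes known as a source of type 2 cytokines. They had been sorted from lungs of naive C57Bl/6 mice aged 6 to 8 weeks, as cells without lineage markers that carried Sca-1, CD127 and CD25 and little or no c-Kit. Arrays of 3 samples lysed straight after the sort were compared with arrays of 2 samples cultured for 3 days with PMA, a phorbol ester that activates protein kinase C, and ionomycin, a calcium ionophore. The comparison shows how expression in cells kept with these 2 activators differed from that in freshly sorted cells. The effects of culture and of stimulation cannot be told apart. The labels give no sex, and Xist differed between the groups, so a difference in sex cannot be separated from these effects either. Pearson correlations across probe sets, which are not independent replicates, were 0.980 to 0.989 between unstimulated arrays, 0.989 between the stimulated arrays and 0.956 to 0.969 between groups. Nothing in the labels says that the samples came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

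Crabp2, which codes for a retinoic acid binding protein, rose 50.7-fold after PMA and ionomycin (5.66 ± 0.49 SE on the log2 scale, n = 3 and 2 arrays). Tnip3, whose product binds the NF-kB regulator A20, rose 38.2-fold (5.26 ± 0.10 SE). The next largest rises among called genes under the naming rule included the isoprenoid enzyme genes Idi2 (12.8-fold) and Idi1 (10.3-fold). The others were the inhibitory receptor genes Havcr2 (11.5-fold) and Tigit (9.44-fold), the transcription factor genes Zbtb32 (9.78-fold) and Irf4 (9.49-fold), the secretogranin gene Scg2 (9.73-fold) and the proenkephalin gene Penk (8.70-fold). Il3 (13.6-fold) and Ccl3 (13.4-fold) differed by more than Idi2 but did not pass the test. Xist, the RNA that coats the inactive X chromosome, fell 45.7-fold, from 9.65 ± 0.56 (SD, n = 3) to 4.13 ± 0.04 (SD, n = 2). The other large falls were in Fosb, a subunit of the transcription factor AP-1 (27.8-fold), the chemokine-like receptor gene Ccrl2 (20.4-fold), Vps37b (14.8-fold), the phosphodiesterase gene Pde7b (12.0-fold), the NKG2D ligand gene H60b (10.9-fold), Samd9l (10.7-fold), the MAP kinase phosphatase gene Dusp1 (10.3-fold), the IL-25 receptor gene Il17rb (9.35-fold) and the adaptor gene Fyb (8.51-fold). The lower group means of Xist, Idi2 (4.17) and H60b (4.15) lay under the lower quartile of all probe sets (4.51), so their folds may be lower bounds. Adjusted p-values of these 20 genes ran from 0.0105 for Fosb to 0.0496 for Scg2. In all, 147 genes rose and 192 fell among 19938, of which 63 and 121 did so by 2-fold or more. Each of the 339 called genes had groups that did not overlap, as had 32.5% of all genes. A chance split separates a single gene with a probability of at most 20%. Genes vary together across 5 arrays, so the share over all genes can lie above that by chance. The counts moved with every array left out: limma called 2 genes higher and 5 lower without unstimulated array 1, 45 and 43 without unstimulated array 3, 343 and 208 without stimulated array 1, 361 and 413 without stimulated array 2, and none without unstimulated array 2 (3024 at an unadjusted p under 0.05). All 339 genes kept their sign in those 5 fits, which was fixed in advance because their groups did not overlap. A filter for genes above the median of all probe sets gave 826 higher and 715 lower. Centring each array on its median gave 660 and 526, or 55.6% higher against 43.4%.

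Among the secreted products of helper-type innate lymphoid cells, Penk, Il4 and Il9 rose, and none of the 13 measured members fell. Il4 rose 7.30-fold from an unstimulated level of 7.38 ± 0.26 (SD, n = 3), a difference of 2.87 ± 0.18 SE (adjusted p = 0.0323), and Il9 rose 4.57-fold (2.19 ± 0.15 SE, adjusted p = 0.0352). Differences in Il3 (3.76 ± 0.49 SE, adjusted p = 0.0652), Il10 (2.93 ± 0.29, adjusted p = 0.0508) and Il13 (2.41 ± 0.43, adjusted p = 0.0942) did not pass the test. Il5 was already at 9.89 ± 0.48 (SD, n = 3) in unstimulated cells, and its difference of 0.71 ± 0.33 did not pass (adjusted p = 0.382). The differences in Csf2 (-0.79 ± 0.09, adjusted p = 0.0566) and Il2 (-1.88 ± 0.37, adjusted p = 0.110) did not pass either. There were 6 members higher and 2 lower adjusted over the list alone. The list as a whole was higher (median 0.71, camera adjusted p = 0.01), with adjusted p = 0.517 with an estimated correlation. Without stimulated array 1 its adjusted p was 0.0612, and its median was 0.43 without unstimulated array 3 and 1.27 against unstimulated array 3 alone.

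Of 14 measured cytokine and alarmin receptor genes, 6 fell and none rose: Il17rb (-3.23 ± 0.32 SE), Il9r (-2.01 ± 0.15), Il4ra (-1.99 ± 0.17), Il18r1 (-1.85 ± 0.13), the interferon gamma receptor gene Ifngr1 (-1.38 ± 0.06) and Il10ra (-0.84 ± 0.07), with adjusted p from 0.0229 to 0.0492. The list members Il1rl1 and Il2rg were not measured, and Crlf2 differed by 0.02 ± 0.07 (adjusted p = 0.933). The count of lower genes was 9 adjusted over the list alone. The list's median was -0.82 (camera adjusted p = 6.99e-09; adjusted p = 0.261 with an estimated correlation). The 5 measured sort marker genes were Kit, Il7r and Il2ra of the gate and the further leukocyte markers Ptprc and Thy1. The gene of Sca-1, Ly6a, was not measured. A gene used to select cells is no finding in its unstimulated level. Kit fell from 9.85 to 6.98 (-2.86 ± 0.13 SE). Its unstimulated value lay above the upper quartile of each unstimulated array (7.03 to 7.11), although the gate took cells with little or no c-Kit protein. Il7r, which codes for CD127, fell by 0.77 on the log2 scale (SE 0.03), and both had adjusted p = 0.0229. Il2ra, which codes for CD25, differed by 0.19 ± 0.04 (adjusted p = 0.101), Ptprc by 0.03 ± 0.04 and Thy1 by -1.34 ± 0.16 (adjusted p = 0.0582). Of the 5, 1 was higher and 3 lower adjusted over the list alone. The sort markers were lower as a list (median -0.77, camera adjusted p = 0.0243), with adjusted p = 0.332 with an estimated correlation, 0.0762 without unstimulated array 3, 0.114 without stimulated array 1 and 0.112 against unstimulated array 3 alone.

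Among 15 measured transcription factors of the lineage, Id2 (-0.78 ± 0.05 SE, adjusted p = 0.0352) and Rora (-0.81 ± 0.07, adjusted p = 0.0456), both required for these cells to develop, fell, and none rose. Gata3, the main regulator of type 2 cytokine genes, stood at 10.7 ± 0.14 (SD, n = 3) and 10.2 ± 0.03 (SD, n = 2), a difference that did not pass the test (-0.51 ± 0.10, adjusted p = 0.107). Lmo4 had the widest difference of the list (-2.48 ± 0.25, adjusted p = 0.0510), and the list member Tcf7 was not measured. Adjusted over the list alone, 1 member was called higher and 5 lower. The list was lower (median -0.51, camera adjusted p = 0.000113), with adjusted p = 0.517 with an estimated correlation and 0.0716 against unstimulated array 3 alone.

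**Figure D1:**
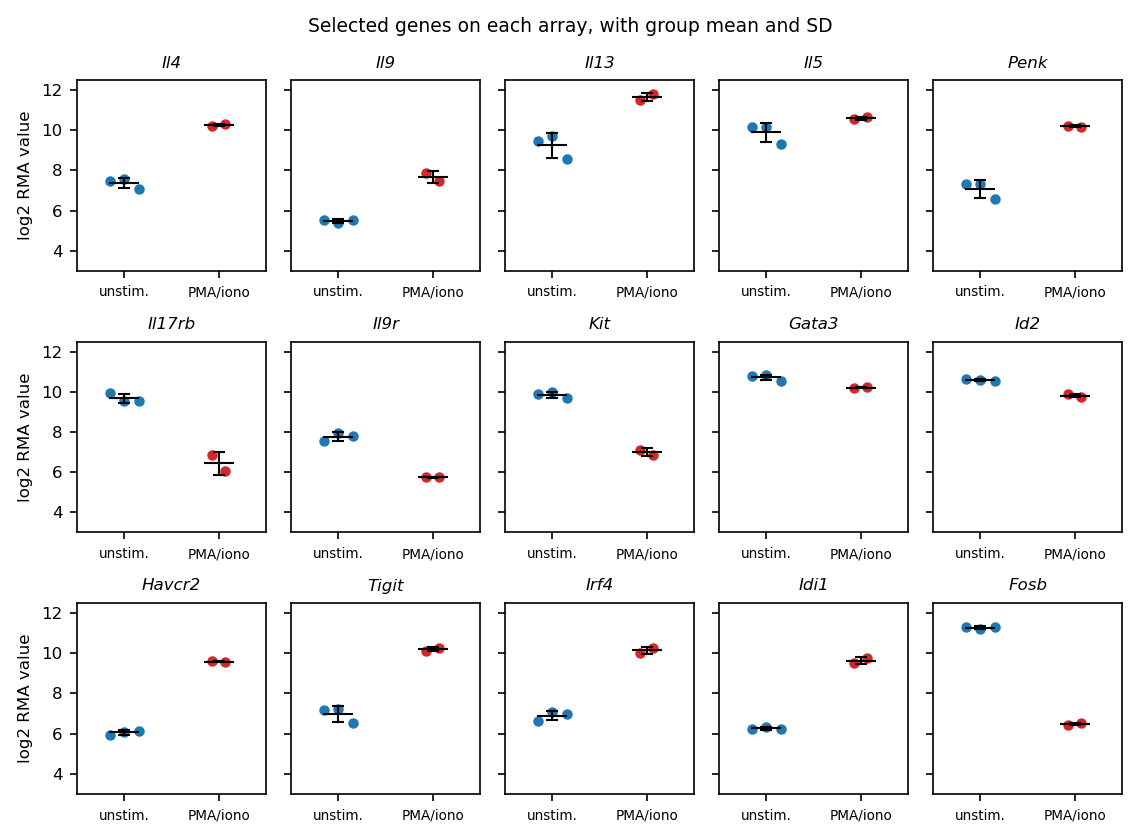
The log2 RMA value of 15 genes on each array, with unstimulated arrays in blue, PMA and ionomycin arrays in red, and bars for the group mean and SD (n = 3 and 2). Both stimulated values of Havcr2 lie above all 3 unstimulated values by over 3 log2 units, while those of Gata3 lie below by 0.51 on average, a difference that did not pass the test.

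Immediate early genes, which mark recent activation or stress and were listed for their known rise during tissue dissociation, were lower in the cultured cells. Of 18 measured, 9 fell and none rose, among them Fosb (-4.80 ± 0.06 SE), Dusp1 (-3.36 ± 0.15), Fos (-2.95 ± 0.11) and Jun (-2.89 ± 0.21). In all, 14 were lower adjusted over the list alone. The median was -1.96 (camera adjusted p = 7.21e-14; adjusted p = 0.261 with an estimated correlation). Among 17 NFAT and NF-kB activation genes, Irf4 rose (3.25 ± 0.17) and the NF-kB inhibitors Tnfaip3 (-2.14 ± 0.09) and Nfkbia (-2.06 ± 0.19) fell. Adjusted over the list alone, 5 were higher and 6 lower, and the list as a whole was not called (median -0.24, camera adjusted p = 0.134), except without unstimulated array 3 (adjusted p = 0.0182) and after median centring (adjusted p = 0.0496). Its median was -0.12 without unstimulated array 1, -0.37 without unstimulated array 3 and -0.04 against unstimulated array 3 alone. Of 18 signalling feedback inhibitors, Cish fell (-0.53 ± 0.05), and the list was not called (median 0.14, mean -0.03, camera direction up, adjusted p = 0.944), with 1 higher and 3 lower adjusted over the list alone. Its median was 0.05 without unstimulated array 3 and 0.07 without stimulated array 2.

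Of 18 measured costimulatory and inhibitory receptor genes of lymphocytes, Havcr2 (3.52 ± 0.08 SE), Tigit (3.24 ± 0.27), Tnfrsf9, which codes for 4-1BB (2.88 ± 0.07), and Lag3 (2.81 ± 0.21) rose, and none fell. Adjusted over the list alone, 7 were higher and 4 lower, and the list was not called (median 0.30, camera adjusted p = 0.0967; adjusted p = 0.562 with an estimated correlation) except without unstimulated array 2 (adjusted p = 0.0295), against unstimulated array 3 alone (adjusted p = 0.0322), after centring on the reference genes (adjusted p = 0.000884) and with fry (adjusted p = 0.0166). Its median was 0.09 without unstimulated array 3 (adjusted p = 0.289) and 0.49 against unstimulated array 3 alone. Of 20 chemokine genes, Ccl4 rose 2.14-fold (1.10 ± 0.08), and no other was called over all genes. Adjusted over the list alone, 5 were higher and 3 lower (list median -0.01, mean 0.07, camera direction down, adjusted p = 0.934). The higher ones included Ccl3 (3.74 ± 0.58, adjusted p over all genes 0.0808) and Xcl1 (2.45 ± 0.28, 0.0582). The lower ones were Cxcl10 (-2.99 ± 0.51, 0.0914), Ccl5 (-2.13 ± 0.44, 0.116) and Ccl6 (-1.83 ± 0.31, 0.0897). Among 12 type 1 and type 17 effector genes, the IL-18 receptor gene Il18rap fell (-1.44 ± 0.12). Ifng (2.64 ± 0.92, adjusted p = 0.254) read 9.80 and 7.43 on stimulated arrays 1 and 2 and did not pass the test. Neither did Il17f (2.87 ± 0.30, adjusted p = 0.0526) nor Il17a (2.17 ± 0.49, adjusted p = 0.132). That list had 1 member higher and 1 lower adjusted over the list alone and was not called (median -0.07, mean 0.52, camera direction up, adjusted p = 0.934), and its median was 0.03 without unstimulated array 1, 0.09 without unstimulated array 2, -0.20 without unstimulated array 3 and 0.63 against unstimulated array 3 alone. Of 13 TNF family and cytotoxic ligands, Tnfsf11, which codes for RANKL, fell (-0.86 ± 0.08), with 3 higher and 1 lower adjusted over the list alone (median -0.24, camera adjusted p = 0.276), and a median of -0.13 without unstimulated array 2 and -0.10 against unstimulated array 3 alone.

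Cholesterol synthesis genes were higher after PMA and ionomycin. Of 16 measured, Idi1 (3.37 ± 0.10 SE), Hmgcs1, which codes for HMG-CoA synthase (2.02 ± 0.15), and Cyp51 (1.06 ± 0.06) rose and none fell, and 12 were called higher adjusted over the list alone. The list's median was 0.98 (camera adjusted p = 3.83e-09; adjusted p = 0.345 with an estimated correlation). Of 20 ribosome biogenesis genes, Nop16 rose 2.18-fold (1.12 ± 0.06), none fell, and 15 were higher adjusted over the list alone (median 0.50, camera adjusted p = 1.37e-08; adjusted p = 0.261 with an estimated correlation). Among 18 genes for chaperones of the endoplasmic reticulum and the unfolded protein response, the protein folding genes Pdia6 (1.73 ± 0.14) and Calr (0.56 ± 0.05) rose and none fell, with 9 higher and 1 lower adjusted over the list alone (median 0.44, camera adjusted p = 0.00512; adjusted p = 0.261 with an estimated correlation).

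Energy and amino acid metabolism lists were higher with few single genes called. No gene of the 19 in the respiratory chain and citric acid cycle list passed on its own, 7 were higher adjusted over the list alone, and the median was 0.54 (camera adjusted p = 3.01e-06; adjusted p = 0.517 with an estimated correlation). In the glycolysis list of 14, the triose phosphate isomerase gene Tpi1 rose 3.14-fold (1.65 ± 0.11 SE) and the glucose transporter gene Slc2a3 fell (-0.94 ± 0.08), with 7 higher and 1 lower adjusted over the list alone. Its median was 0.44 (camera adjusted p = 0.00537; adjusted p = 0.517 with an estimated correlation, 0.0600 without stimulated array 1). None of the 19 amino acid uptake and serine-folate genes was called, with 9 higher and 2 lower adjusted over the list alone (median 0.39, camera adjusted p = 0.00123; adjusted p = 0.261 with an estimated correlation). Fry did not call the respiratory chain list (adjusted p = 0.0654).

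Genes of the cell cycle were higher on stimulated array 1 more than on stimulated array 2. The median of 20 DNA replication genes was 7.23 on stimulated array 1 and 6.69 on array 2, against 6.06, 6.07 and 6.43 on the unstimulated arrays. For 19 mitosis genes the medians were 6.47 and 5.93, against 5.32, 5.75 and 5.85. No gene of either list was called. Gins1 differed by 2.06 ± 0.59 SE (adjusted p = 0.187), Mki67, a common marker of dividing cells, by 0.03 ± 0.17 (adjusted p = 0.958), and 1 replication gene and no mitosis gene was higher adjusted over the list alone. Both lists were called (medians 0.51 and 0.36, camera adjusted p = 0.00172 and 0.01), with adjusted p = 0.540 and 0.589 with an estimated correlation, 0.178 and 0.282 with fry, 0.194 and 0.613 without stimulated array 1, and 0.139 and 0.432 against unstimulated array 3 alone. The medians were 0.20 and 0.10 without stimulated array 1 and 0.28 and 0.23 against unstimulated array 3 alone, and that of mitosis was 0.61 without stimulated array 2. Mitosis also lost its call without unstimulated array 1 (adjusted p = 0.0993) and among genes above the median (adjusted p = 0.107).

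Of 18 genes for residency, egress and homing, the activation marker gene Cd69 (-2.71 ± 0.16 SE), the G protein regulator gene Rgs2 (-1.96 ± 0.15) and the integrin gene Itga4 (-1.91 ± 0.08) fell and none rose. Adjusted over the list alone, 2 were higher and 8 lower, and the median was -0.42 (camera adjusted p = 0.000291; adjusted p = 0.261 with an estimated correlation). Among 14 survival and cell death genes, the survival genes Bcl2 (-1.02 ± 0.07) and Birc3 (-0.65 ± 0.04) fell, none rose, and 5 were lower adjusted over the list alone (median -0.27, camera adjusted p = 0.00745; adjusted p = 0.332 with an estimated correlation, 0.118 without stimulated array 1 and 0.112 against unstimulated array 3 alone). Its median was -0.10 without unstimulated array 1, -0.15 without unstimulated array 2, -0.10 against unstimulated array 3 alone and -0.42 among genes above the median. Of 18 lipid mediator and neuropeptide genes, the prostaglandin E2 receptor gene Ptger4 (-1.37 ± 0.06) and the vasoactive intestinal peptide receptor gene Vipr2 (-1.33 ± 0.10) fell, and Ptger2, which codes for another prostaglandin E2 receptor, rose (1.07 ± 0.07). Adjusted over that list alone, 1 was higher and 5 lower (median -0.21, camera adjusted p = 0.0266; adjusted p = 0.332 with an estimated correlation). Its call was lost without unstimulated array 3 (adjusted p = 0.0546), stimulated array 1 (0.0506) or stimulated array 2 (0.187), and against unstimulated array 3 alone (0.112), and its median was -0.42 among genes above the median.

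**Figure D2:**
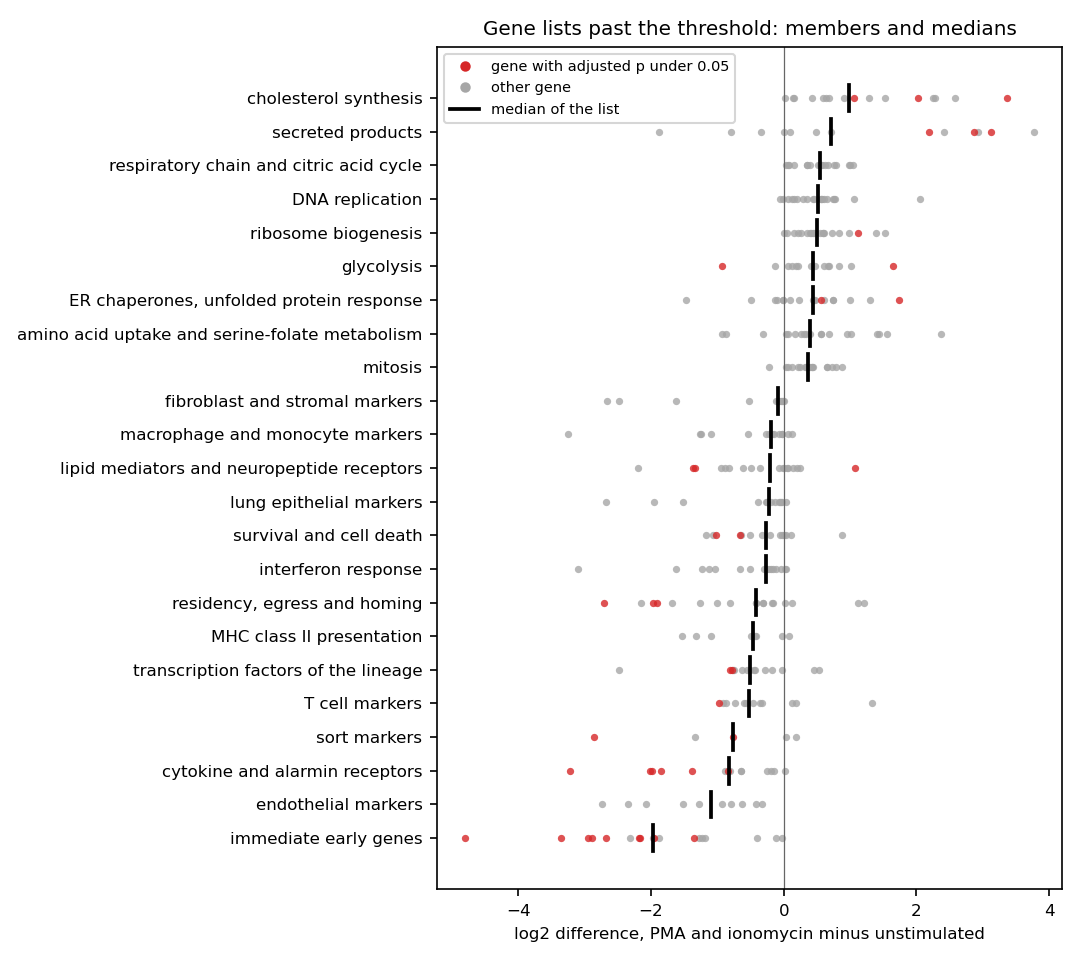
Differences in log2 RMA value, PMA and ionomycin minus unstimulated, for each measured gene (points) of the 9 higher and 14 lower gene lists past the threshold with the preset correlation, with each list's median as a black bar and called genes in red. The immediate early list has the lowest median, -1.96, and cholesterol synthesis the highest, 0.98, and no list kept its call with an estimated correlation.

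Endothelial markers were higher on unstimulated arrays 1 and 2 than on unstimulated array 3, and those of other lung cells mainly on array 1. The median of 10 endothelial markers was 7.31, 6.98 and 5.73 on unstimulated arrays 1, 2 and 3 and 5.43 and 5.51 on the stimulated arrays, and the endothelial cadherin gene Cdh5 read 9.71, 9.06 and 7.12 against 5.59 and 6.19. The median difference of unstimulated array 1 from array 3 was 0.39 for lung epithelial, 0.23 for fibroblast, 0.24 for macrophage and 0.23 for neutrophil markers, and that of array 2 from array 3 was 0.06, 0, 0 and 0.15. Single genes picked after their values were seen spread more widely than their lists, such as the airway secretory gene Scgb1a1 (11.2, 10.6 and 8.67 against 6.95 and 7.97), the stromal gene Sparc (9.73, 9.05 and 7.37 against 5.61 and 6.5) and the neutrophil gene S100a9 (9.49, 8.15 and 6.91 against 4.97 and 5.09). No gene of the endothelial, lung epithelial (14), fibroblast (12), macrophage (14) and neutrophil (12) lists was called, and adjusted over the list alone 2 macrophage genes and 1 neutrophil gene were lower. The first 4 of these lists were lower with camera, with medians of -1.10, -0.22, -0.08 and -0.20 and adjusted p = 0.000562, 0.00639, 0.0133 and 0.00535. With an estimated correlation their adjusted p was 0.517, 0.517, 0.517 and 0.430, and with fry 0.178, 0.232, 0.188 and 0.0595. The lung epithelial and macrophage calls were lost against unstimulated array 3 alone (adjusted p = 0.2 and 0.144), with medians of -0.09 and -0.08, and the endothelial median was -0.34. Without unstimulated array 1 the lung epithelial, fibroblast and macrophage medians were -0.09, -0.04 and -0.13, and without unstimulated array 3 the macrophage median was -0.32. Without stimulated array 1 the lung epithelial and fibroblast calls were lost (adjusted p = 0.0600 and 0.0941, fibroblast median -0.12), as among genes above the median (adjusted p = 0.0974 and 0.0591). In that filter the medians were larger, -0.25 and -1.62 for those lists and -1.17 for the macrophage list, which kept its call (adjusted p = 0.00882). The neutrophil list was not called (median -0.09, camera adjusted p = 0.163), except among genes above the lower quartile (adjusted p = 0.0453), and its median was -0.03 without unstimulated array 1 and -0.20 without stimulated array 1.

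Interferon response and MHC class II genes were also higher on unstimulated arrays 1 and 2 than on unstimulated array 3. Ifit3, an interferon-induced gene, read 9.23, 8.88 and 5.93 on the unstimulated arrays and 5.6 and 4.23 on the stimulated ones, and H2-Ab1, an MHC class II chain gene, 8.43, 8.05 and 6.89 against 6.20 and 6.31. None of the 16 interferon and 8 MHC class II genes was called, over all genes or adjusted over the list alone. Both lists were lower (medians -0.27 and -0.47, camera adjusted p = 0.00274 and 0.0319), with adjusted p = 0.520 and 0.540 with an estimated correlation, 0.277 and 0.266 with fry, and 0.432 and 0.451 against unstimulated array 3 alone, where the medians were -0.04 and -0.01. The interferon median was -0.41 without unstimulated array 3 and -0.48 among genes above the median. The MHC class II call was also lost without unstimulated array 1 (adjusted p = 0.152), unstimulated array 2 (0.0724), stimulated array 1 (0.1) or stimulated array 2 (0.179). Of 12 T cell markers, Themis fell (-0.98 ± 0.07 SE), with 1 higher and 2 lower adjusted over the list alone. That list was lower (median -0.52, camera adjusted p = 0.0330), with adjusted p = 0.589 with an estimated correlation, 0.282 with fry, 0.0901 without unstimulated array 1, 0.227 without unstimulated array 2, 0.0612 without stimulated array 1, 0.178 without stimulated array 2 and 0.0974 among genes above the median. The T cell median was -0.20 without unstimulated array 2 and 0.14 against unstimulated array 3 alone (adjusted p = 0.451).

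The remaining lists were not called. Markers of B cells (median -0.15, 9 genes, camera adjusted p = 0.121), NK cells (-0.23, 11 genes, 0.212), mast cells and basophils (-0.03, 12 genes, 0.239) and dendritic cells (-0.11, 12 genes, 0.0982) held no called gene, and adjusted over the list alone 1 mast cell and basophil gene was lower. B cell markers were called lower without unstimulated array 3 (adjusted p = 0.00994). The NK cell median was -0.36 without unstimulated array 3 and -0.05 without stimulated array 2, and the dendritic cell median -0.04 without unstimulated array 2 and -0.19 without stimulated array 2. The 3 measured erythroid markers had a median of -0.01 and were too few to test. The 10 measured reference genes had a median of 0.16 and a mean of 0.18, and none was called.

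Y-linked genes were measured on every array beside Xist. Eif2s3y read 8.76, 7.15 and 7.98 on unstimulated arrays 1, 2 and 3 and 8.48 and 8.37 on the stimulated arrays, and Kdm5d read 6.81, 5.69 and 6.62 against 7.41 and 7.42. Xist read 9.09, 10.2 and 9.66 against 4.16 and 4.11. The differences in Eif2s3y (0.46 ± 0.55 SE, adjusted p = 0.654), Kdm5d (1.04 ± 0.40, adjusted p = 0.299) and Uty (-0.12 ± 0.65, adjusted p = 0.963) did not pass the test. The labels do not give the sex of the mice.

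**Figure D3:**
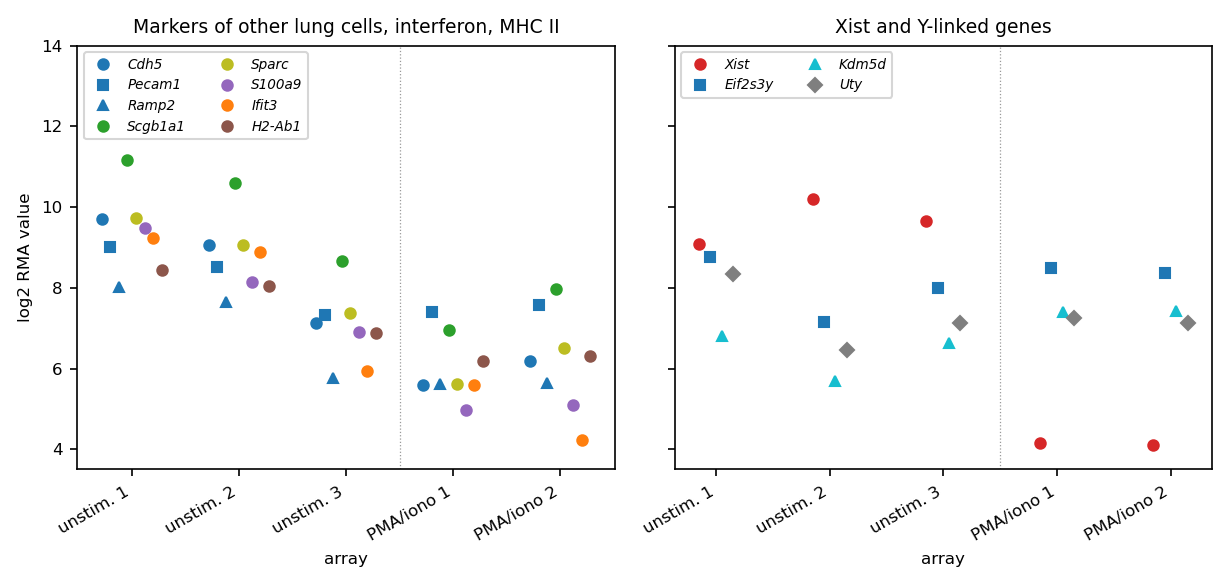
Log2 RMA values on each of the 5 arrays for markers of other lung cells, an interferon-induced gene and an MHC class II gene (left) and for Xist and Y-linked genes (right), with points of different genes offset sideways. Cdh5 reads 9.71 and 9.06 on unstimulated arrays 1 and 2 and 7.12 on array 3, and Xist lies above 9 on all unstimulated arrays and near 4 on both stimulated arrays.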

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

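Both results in this part were found after seeing the data, in a fit of every probe set of the array, named or not. Among the 12146 probe sets absent from the annotation table used here, 83 passed an adjusted p under 0.05, 32 of them higher and 51 lower after PMA and ionomycin. The 2 with the largest differences were probe 10339276 (-3.43 ± 0.22 SE, adjusted p = 0.0371) and probe 10401935 (-3.18 ± 0.25 SE, adjusted p = 0.0459), each lower on 2 of 2 stimulated arrays than on all 3 unstimulated ones. Among the 1621 probe sets with several gene symbols, 10 passed, 3 higher and 7 lower. Neither kind of probe set passed more often than all probe sets together. These signals lie in probe sets that the report's comparison did not use, and no explanation for them was tested.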

How the results depend on the processing

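The 3 added settings were chosen after seeing the data: unstimulated array 3 alone against the stimulated arrays, no genes with repeated values, and no lists of other cell types, interferon or sex-linked genes. The other settings were planned. Main counts were 147 genes higher and 192 lower, and 9 lists higher and 14 lower.

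The gene counts were 45 and 66 with robust variances, 826 and 715 among genes above the median of all probe sets, and 319 and 356 above the lower quartile. They were 660 and 526 with median centring, 825 and 729 with quantile normalization applied again, 619 and 666 with cyclic loess and 1048 and 1815 with centring on the reference genes. That last scaling shifted the median of all genes by -0.18 and turned the sign of 2 of the 339 called genes. Without genes holding repeated values, 1548 and 1161 of 7579 genes were called. The prior degrees of freedom, 0.649 in the main fit, were 3.51 there and 6.77 with reference centring. Limma called 5 and 2 genes with treat against 1.5-fold, 63 and 121 at 2-fold or more, and 0 and 0 at an adjusted p under 0.01, where 3973 had an unadjusted p under 0.05. Unstimulated array 3 alone left 0 and 0 (3739 at an unadjusted p under 0.05), with the lone array assumed to vary like the stimulated pair. Leaving out 1 array gave 0 to 361 higher and 0 to 413 lower, where a lone stimulated array was assumed to vary like the unstimulated ones. A trend, array weights, the mean of a gene's probe sets, every probe set, and the fit without other cell types stayed within 1.5 times the main counts. Apart from fewer genes or arrays, the cause of these shifts was not tested.

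A check of the replicate numbers could not decide on pairing. Deviations from the group means correlated at -0.145 for number 1 and -0.058 for number 2. Deviations of 2 stimulated arrays mirror each other, so unstimulated arrays 1 and 2 gave 0.145 and 0.058 with the other number. With the replicate block, limma called 0 genes higher and 0 lower (3568 at an unadjusted p under 0.05). The list counts stayed at 9 and 14, with sort markers and lipid mediators losing their calls and B cell and dendritic cell markers gaining one.

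With an estimated correlation, 0 lists were higher and 0 lower, a setting that recovered 21 of 40 simulated moved lists, whose genes varied independently. Fry called 7 higher and 7 lower. Unstimulated array 3 alone gave 8 lists higher and 5 lower, with mitosis and DNA replication lost and costimulatory receptors gained among the higher ones, and T cell markers turning to a median of 0.14, and the fit without the other cell types' lists left 8 lower, since it removed lists. Leaving out 1 array gave 5 to 10 lists higher and 7 to 14 lower, the fewest without stimulated array 1. The 4 normalizations ended 3 list calls, of T cell markers with cyclic loess and with reference centring (adjusted p = 0.163) and of MHC class II with reference centring (adjusted p = 0.0543), and turned no called list. There were no detection calls, and how far signal over background limits these counts was not tested.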

Other observations

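The lists in the next 2 paragraphs were chosen after the table of all genes had been seen, so their directions are not independent evidence, and the tests on endothelial markers and on lung cells as a source of immediate early genes were also chosen afterwards. The tests on heat shock factor targets and on X-linked escape genes were written before their values were seen.

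Genes for protein synthesis and turnover were higher after PMA and ionomycin. The proteasome list does not hold every subunit gene. All 24 of its genes were higher on both stimulated arrays than on every unstimulated array. Their median was 0.78, Psmd11 was called over all genes (0.92 ± 0.09 SE, adjusted p = 0.0492), and 24 were higher adjusted over the list alone. Of 18 aminoacyl-tRNA synthetase genes, 16 were higher on both stimulated arrays (median 0.81), and Tars (1.29 ± 0.04), Yars (0.78 ± 0.07), Nars (0.78 ± 0.05) and Wars (0.50 ± 0.04) rose. Adjusted over the list alone 15 were higher and 1 lower, Eprs (-0.91 ± 0.26). Of 28 genes for N-glycosylation and entry into the endoplasmic reticulum, 22 were higher on both (median 0.57), and Dpagt1, the first enzyme of that glycan pathway, rose (1.36 ± 0.13), with 19 higher and 1 lower, Stt3b (-0.80 ± 0.19), adjusted over the list alone. Of 19 fatty acid synthesis genes, 12 were higher on both (median 0.43), with Scd2 rising (0.88 ± 0.09) and Elovl5 falling (-1.72 ± 0.16), with 8 higher and 1 lower adjusted over the list alone and a median of 0.29 without stimulated array 1. Camera's adjusted p over 6 such lists was 1.86e-13, 1.43e-09, 1.43e-09 and 0.000172, and 0.164, 0.130, 0.164 and 0.130 with an estimated correlation.

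Targets of the transcription factor FOXO1, which PI3 kinase signalling is known to switch off, were lower. Of 19 measured, 18 were lower on both stimulated arrays than on every unstimulated array, with a median of -0.55. Txnip (-2.28 ± 0.06 SE, adjusted p = 0.0168), Tsc22d3 (-0.77 ± 0.05) and Il7r (-0.77 ± 0.03) fell, and 10 were lower adjusted over the list alone. The list was called with camera (adjusted p = 2.84e-11; adjusted p = 0.130 with an estimated correlation). S1pr1, also known from endothelial cells, read 9.97, 9.51 and 7.80 on the unstimulated arrays and 6.96 and 6.92 on the stimulated ones. Against unstimulated array 3 alone the list's median was -0.38.

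Endothelial markers were lower after PMA and ionomycin, and the unstimulated arrays differed among themselves. Culture cannot account for the differences among the unstimulated arrays, which were all lysed fresh. A median share of 0.715 of the drop from unstimulated array 1 to the stimulated mean was already there between unstimulated arrays 1 and 3. That share was 0.700 to 0.729 leaving out each of 10 markers. It cannot decide whether culture caused the fall, because unequal levels could all have fallen in culture. Lung endothelial cells or their RNA in unequal amounts may be a source. The markers' median was 1.32 higher on unstimulated array 1 than on array 3 (random lists -0.12 to 0.10), with Cdh5, Pecam1 and Ramp2 at 9.71, 9.01 and 8.02 on array 1. These arrays had already been seen to differ, so that value restates the pattern and cannot decide its source. MHC class II (0.66), interferon (0.46), T cell (0.44), NK cell (0.25) and B cell (0.17) lists also lay above their random lists there. So did the lung epithelial (0.39), macrophage (0.24), fibroblast (0.23) and neutrophil (0.23) lists. Mast cell and basophil markers and dendritic cell markers had medians of 0. The sort on CD127 and CD25 would be thought to remove endothelial cells, Pecam1 is also known from leukocytes, and no other list holds these genes. A fall in culture stays open, and the median against unstimulated array 3 was still -0.34 (random lists -0.10 to 0.14).

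Immediate early genes were lower after PMA and ionomycin by medians of -2.17, -2.04 and -1.73 against unstimulated arrays 1, 2 and 3. Other lung cells that varied like the endothelial markers go against these values as the whole cause. The endothelial medians shrank from -1.52 to -0.34 from array 1 to array 3. The immediate early median of -1.73 against array 3 stayed below that of random lists (-0.13 to 0.29). Cells held in like amounts on all unstimulated arrays would not show in this test. Digestion and sorting may have raised these genes in the freshly lysed cells. Heat shock factor targets, which that handling is known to raise too, had a median difference of 0.26, inside the range of random lists (-0.20 to 0.34) with members going both ways (camera adjusted p = 0.331; adjusted p = 0.543 with an estimated correlation). After centring on the reference genes camera called these targets higher (adjusted p = 0.0177) with a median of 0.08. Handling before lysis and a decline during 3 days of culture cannot be told apart here, because all unstimulated samples were lysed fresh and all stimulated ones cultured.

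Xist was lower on both stimulated arrays, and Y-linked genes were present on all 5. The unstimulated array with the highest Xist value, array 2, had the lowest Eif2s3y, Kdm5d and Uty values. On array 1, Eif2s3y (8.76 against 8.48 and 8.37) and Uty (8.35 against 7.25 and 7.13) were above both stimulated arrays. Kdm5d was below both there (6.81 against 7.41 and 7.42), as on the other unstimulated arrays. Unstimulated samples drawn from both sexes and stimulated samples from males may account for this, as may a loss of Xist RNA on activation with an unchanged sex make-up. The test on 4 measured X-linked genes that escape inactivation gave a median change of 0.0314 (SE of the mean over genes 0.20). Members went both ways, with Ddx3x falling (-0.70 ± 0.06 SE) and Eif2s3x at 0.18, Pbdc1 at 0.15 and Kdm5c at -0.09. Kdm6a, which also escapes, was left out of that test because its values had been seen, and it was lower on both stimulated arrays (-1.16 ± 0.12 SE, adjusted p = 0.0520). With it the median of 5 genes was -0.09 (SE of the mean over genes 0.26). The 2 explanations cannot be told apart, since these genes are few and go both ways, and the labels give no sex. If the groups differed in sex, each gene and list difference in the report would be confounded with it.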
